A study of Homo sapiens with 4 samples.

How the data were processed

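ATAC-seq libraries were made from 50000 HCT116 cells each, 2 after 6 h in tunicamycin and 2 after 6 h in DMSO, per the labels' protocols. The submitters' processing notes name Trim Galore, Bowtie2 2.3.5.1, SAMtools, Picard 2.18.23, deepTools, MACS2 2.2.7.1 and the hg19 build, without their order or settings. The settings of the peak caller, any shift of reads for the transposase offset, and any filter on peaks are not given in the sources used here. The authors deposited 1 peak list per library, called on that library alone as far as the names of the peaks show. Each list holds the position of a peak, a whole-number score, a fold, 2 −log10 values and the distance of the summit from the start of the peak.

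In the deposited lists the score was the whole part of 10 times the −log10 q-value for at least 99.95% of peaks, and the −log10 q-values began at 1.30. The deposited fold is a ratio of the summit pileup to the local background, each plus 1, within the library, and the deposited −log10 p-value is the Poisson tail of that pileup. This reading was tested on the files: for 100% of peaks in every library, a whole-number pileup and a background existed that gave the fold and matched the −log10 p-value within 0.001. The background of the peaks at the lowest level is the genome-wide one. It moves with the number of reads and the length to which they were extended, so it measures relative depth only if that length was the same in the 4 libraries. The read totals were not used here. The folds and −log10 values are the authors' own, and were used to describe, rank or filter peaks within their list.

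Peak numbers in the deposited names ran to 57232, 57226, 59143 and 63249 for DMSO replicates 1 and 2 and tunicamycin replicates 1 and 2. Between 1.14% and 1.15% of the numbers were not listed in each library. The lists held peaks on 23 sequences (chromosomes 1 to 22 and X) and no overlapping peaks within a list. The smallest width was 100 bp in each library. If this is a limit of the lists, a peak under that width in a library would be missing. Low summit counts limit the rest: the median summit pileup, as recovered from the fold and p-value, was 15 or 16. Many calls near the threshold therefore rest on a pileup under 10. The pileup is given as reads throughout, although what the caller piled up, and how far it was extended, is not known. Intervals cover counting error only: they treat regions as independent and hold no variation between libraries.

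Libraries were grouped by their titles. The lists were merged into regions wherever peaks shared at least 1 bp, and each region was classed by the libraries that listed a peak in it (Python 3.11.15, pandas 2.3.3, numpy 2.4.6). The number of peaks was compared by a two-sided exact permutation test (scipy 1.17.1). Presence in a list gives no test per region with 2 libraries per group, so gained and lost regions were set beside the 4 mixed patterns and beside the other 2 splits of the libraries. Shares were compared by two-sided Fisher's exact test with Benjamini-Hochberg adjustment. The rule for named regions, fixed before the data were examined, took the 12 gained and the 12 lost regions with the best mean percentile rank of the q-value over the lists that held them. The merging step was tested on simulated lists and returned 1900 of 1900 planted regions with their pattern.

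The rank comparison was added after the data had been examined. For every region listed in all 4 libraries the peak with the best q-value per library was taken, ranks were turned into normal scores, and tunicamycin and DMSO were compared with limma 3.58.1 (R 4.3.3), with a prior spread that follows the mean score and Benjamini-Hochberg adjustment at 0.05. Every region called is shown in the plot of ranks, and those described in the text were picked after their values had been seen. On simulated data for this comparison over 40447 regions, with 200 regions shifted, the test recovered 86.5% of shifts of 2 normal-score units with 3 unchanged regions called, and 0% of shifts of 1 unit. It called 0 regions where none was shifted. The simulation gave every region the same spread, so it does not test the prior spread that follows the mean score.

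Alternatives fixed before the data were examined were stricter q-values (−log10 q of at least 5 and 10), lists of equal length, membership above the 50th percentile of both lists, a reciprocal overlap of 50%, merging of peaks up to 250 bp apart, all sequences, each library left out, and the replicate number as a block. Alternatives added after the data were examined were a −log10 q of at least 20, the top 40000, 20000 and 10000 peaks, folds of at least 6, 8, 10 and 15, widths of at least 130, 150 and 200 bp, membership above the 25th, the 40th, the 60th and the 70th percentile of both lists, and the settings of the rank comparison. The limit of 130 bp for narrow peaks was chosen at the same stage, and no other limit was tried for it. The planned comparisons of promoter shares, of 14 gene lists and of 23 sequence motifs near gained and lost regions were not run, because the reference used here holds only a GRCh38 gene table and the peaks are on hg19. For the same reason the genes that were to be named in every case are not reported here.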

Results

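Chromatin accessibility was mapped by ATAC-seq, in which a transposase cuts open chromatin and inserts sequencing adapters, in wild-type HCT116 cells, a human colorectal cancer cell line. The cells had been exposed for 6 h to tunicamycin at 0.5 µg/ml or to 0.1% DMSO, the solvent control. Tunicamycin blocks the first step of protein N-glycosylation, so that unfolded glycoproteins accumulate in the endoplasmic reticulum (ER). Each group held 2 libraries, numbered 1 and 2 and described by the series as biological replicates. The data were 1 list of accessible peaks per library on hg19, with no read totals. The comparison asked which regions of open chromatin differed between cells under ER stress and control cells. Genes near the regions were not assigned here, because no hg19 annotation was used, and regions are therefore named by position. In what follows a gained region had a peak in both tunicamycin libraries and in neither DMSO library, a lost region had the reverse, and a mixed region had a peak in exactly 1 DMSO and 1 tunicamycin library. No treatment effect predicts mixed regions, so their number served as the background.

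Open chromatin covered a similar and small part of the genome in the 4 libraries, with somewhat more peaks after tunicamycin. The DMSO lists held 56581 and 56566 peaks (mean 56574 ± 10.6, SD, n = 2), and the tunicamycin lists held 58467 and 62526 (60497 ± 2870, SD, n = 2). Peaks covered 10.5 ± 0.0362 Mb (SD, n = 2) after DMSO and 11.2 ± 0.628 Mb (SD, n = 2) after tunicamycin. The median peak was 160 bp wide in both DMSO libraries, 159 bp in tunicamycin replicate 1 and 161 bp in tunicamycin replicate 2. The group means of the number of peaks differed by 6.93%, and most of this came from tunicamycin replicate 2, without which the difference was 1.03-fold. In a two-sided exact permutation test the number of peaks gave p = 0.333, which is the smallest value that 2 libraries against 2 allow. Read totals were not used here. The genome-wide background that the authors' fold and p-values imply was 0.140 and 0.147 reads per position in the DMSO libraries and 0.140 and 0.143 in the tunicamycin libraries, and the median summit carried 15 reads in 3 libraries and 16 in tunicamycin replicate 2.

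Most accessible regions were common to stressed and control cells. Merging the lists gave 78788 regions, of which 40447 (51.3%) had a peak in all 4 libraries. These common regions were the strong ones, with a median percentile rank of 61.9 in their own lists and a median mean peak width of 183 bp. Libraries of 1 group overlapped slightly more than libraries of different groups. The Jaccard index over bases was 63.8% between the DMSO libraries and 64.7% between the tunicamycin libraries, against 62.8% to 63.1% for the 4 pairs across groups (62.9% ± 0.140, SD, n = 4 pairs). The gap between the means was 1.34 percentage points. Pairs that share a library are not independent, and no test was made of this gap.

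Tunicamycin was accompanied by 2878 gained and 1462 lost regions. Both tunicamycin libraries thus shared 1.81 times as many peaks absent from DMSO as the mean of the 4 mixed patterns, which held 1279 to 1886 regions each (mean 1589 ± 341, SD, n = 4 patterns). Lost regions, at 0.920 times that mean, lay within the range of the mixed patterns. The mixed patterns followed list length: those with tunicamycin replicate 2, the longest list, held 1886 and 1883 regions, and those with tunicamycin replicate 1 held 1308 and 1279. Lost regions join the 2 shortest lists, and gained regions the 2 longest, so the mean is not a like background for either. Gained regions made up 66.3% of the gained and lost regions together (Wilson 95% interval 64.9% to 67.7%, for counting error only), a ratio of gained to lost regions of 1.97. This ratio was 1.15 without DMSO replicate 1, 1.16 without DMSO replicate 2, 3.06 without tunicamycin replicate 1 and 1.77 without tunicamycin replicate 2. A group left with 1 library needs a peak in that list only, while the other group still needs 2. Gained and lost regions are then defined unequally, so these 4 ratios are not comparable with 1.97. The ratio was 4.23 with every list cut to a −log10 q of at least 20, and 4.36 with a fold of at least 15. Both limits were chosen after the data had been examined. A region could then count as gained or lost although the other group listed a peak below the limit. The lists also differed more in length: the mean number of peaks after tunicamycin was 1.17-fold and 1.22-fold that after DMSO. With every list reduced to its 56566 top-ranked peaks, 2122 regions were gained and 1951 lost, so that the gained share was 52.1% (50.6% to 53.6%). Equal totals push the numbers gained and lost toward each other by construction. A peak below the cut also counted as absent, so some regions counted as lost had a tunicamycin peak in the full lists. The numbers gained and lost both lay above the 4 mixed patterns, which then held 1439 to 1518 regions (1481 ± 34.6, SD, n = 4 patterns). With each list cut to its top 20000 peaks, 803 regions counted as gained and 803 as lost, against 647 to 668 per mixed pattern. In the full lists only 81 gained and 33 lost regions lay above the 60th percentile of both lists. Most of the 803 each way therefore had a weaker peak in the other group. Counting gained and lost regions together, the treatment split gave 4340 regions, or 4073 with lists of equal length. The other 2 ways of dividing the 4 libraries into pairs gave 3191 and 3165, or 2968 and 2957 with lists of equal length. With 3 possible splits, a share of splits below 0.333 cannot be reached.

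**Figure D1:**
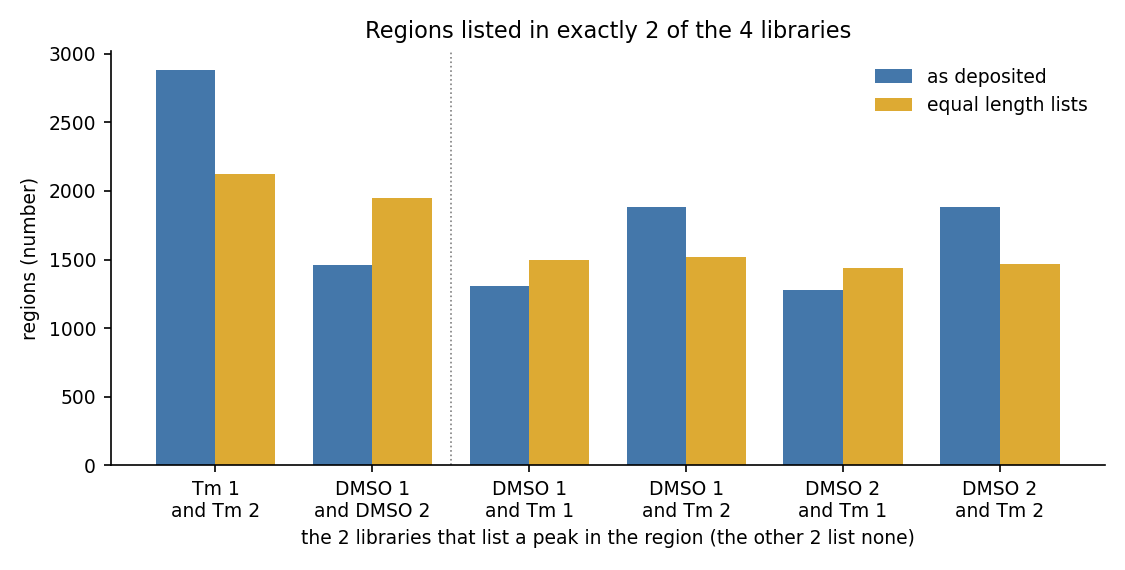
Number of regions (vertical axis) with a peak in exactly 2 of the 4 libraries, by the pair of libraries that list them (horizontal axis), for the lists as deposited and for lists of equal length; the dotted line separates gained and lost regions from the 4 mixed patterns. With lists of equal length, where a peak below the cut counts as absent, the 2122 gained and 1951 lost regions both stand above the mixed patterns, which range from 1439 to 1518.

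Gained and lost regions were weak and narrow sites. In the tunicamycin libraries the median gained region carried 9 reads at its summit in both replicates, a fold over local background of 6.91 in replicate 1 and 7.0 in replicate 2 (the authors' own value per peak). It lay at percentile rank 20.3 in replicate 1 and 21.7 in replicate 2. Lost regions had a median of 8 reads in both DMSO libraries and lay at percentile ranks 18.1 and 18.8. Mixed regions had similar ranks, from 16.4 in DMSO replicate 2 to 20.4 in tunicamycin replicate 2. Common regions, by contrast, had medians of 18 to 21 reads. In each library the smallest summit of a listed peak had 3 reads, so absence from a list means that no peak passed the caller, not that no reads were present. Only 170 gained and 52 lost regions ranked above the 50th percentile in both lists that held them, beside 49 to 85 for each mixed pattern.

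The strong gained regions were narrow too. No listed peak was under 100 bp wide. Among regions above the 50th percentile in every list that held them, a mean peak width under 130 bp, a limit chosen after the data had been examined, was found for 62.9% of the 170 gained regions (Wilson 95% interval 55.5% to 69.8%) and 65.4% of the 52 lost regions (51.8% to 76.8%). It was found for 74.7% of the 269 mixed regions (69.2% to 79.5%) and for 4.0% of the 19387 common regions (3.73% to 4.28%). By two-sided Fisher's exact test with Benjamini-Hochberg adjustment over 6 comparisons, gained regions differed from common regions (adjusted p = 1.14e-100) and were narrow less often than mixed regions (adjusted p = 0.0152). Gained and lost regions were not distinguished (adjusted p = 0.869). These tests count regions and therefore compare the 4 libraries, not the conditions. In 251 gained and 153 lost regions the peaks were at least 150 bp wide in both lists, and the other group listed no peak of any width. Such wide regions made up 8.72% of gained and 10.5% of lost regions, beside 4.93% to 7.0% of the mixed patterns.

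**Figure D2:**
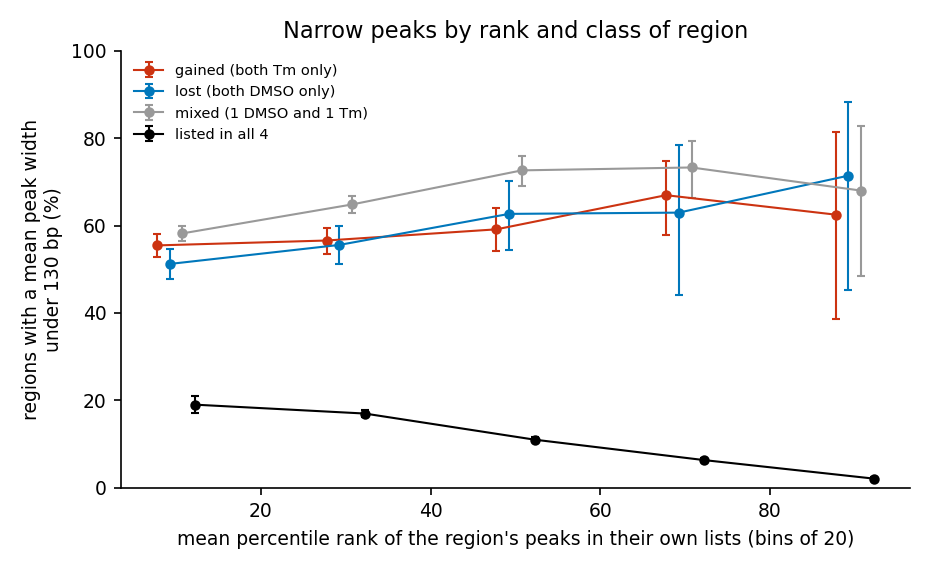
Share of regions with a mean peak width under 130 bp (vertical axis, %) by the mean percentile rank of their peaks (horizontal axis, bins of 20), for gained, lost, mixed and common regions; bars are Wilson 95% intervals and points are offset sideways for legibility. In the top bin the share is 62.5% of 16 gained, 71.4% of 14 lost and 68.0% of 25 mixed regions, against 2.11% of common regions.

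The 12 highest-ranked gained regions lay on chromosomes 2, 3, 4, 5, 7, 8 and 9, and spanned 112 to 215 bp, with 4 of them spanning under 130 bp. This span joins the peaks of both lists and is not the mean peak width used above. A region on chromosome 3, for example, spanned 134 bp with peaks of 110 bp and 127 bp. The strongest was on chromosome 8 at 126475815 to 126475938, with 45 reads at its summit in tunicamycin replicate 1 and 51 in replicate 2 and a mean percentile rank of 97.6. The next, on chromosome 8 at 145550311 to 145550525, had peaks of 208 bp and 214 bp and summits of 38 and 53 reads. Its centre lay 239 bp from that of a common region. A region on chromosome 2 at 135883151 to 135883312 had summits of 37 and 42 reads, with peaks of 153 bp and 157 bp, and its nearest common region was 73423 bp away. The 3 regions after these lay on chromosome 3 at 101522126 to 101522259, on chromosome 8 at 80935936 to 80936096 and on chromosome 2 at 194831450 to 194831567, with mean percentile ranks of 96.0, 94.8 and 93.4. A region on chromosome 5 at 179248740 to 179248892 had summits of 37 and 48 reads over a higher local background, with local folds of 15.1 and 18. The remaining 5 had mean percentile ranks of 82.7 to 88.2. They lay on chromosome 2 at 69064513 to 69064624 and at 239279545 to 239279669, on chromosome 9 at 37840693 to 37840822, on chromosome 7 at 66490559 to 66490690 and on chromosome 4 at 106321054 to 106321199. Of these 12 regions, 3 were still gained when every list was restricted to peaks of at least 130 bp, 2 at 150 bp and 1 at 200 bp, limits chosen after the data had been examined. The widths of their own tunicamycin peaks fixed these counts, since a region dropped out when either peak was under the limit. The counts therefore say nothing about signal in the DMSO libraries. With peaks up to 250 bp apart merged, 11 of the 12 were still gained.

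The 12 highest-ranked lost regions spanned up to 235 bp, and 9 of them spanned under 130 bp. This too is the joined span of both lists, not the mean peak width. The 9 lost and the 4 gained regions with a span under 130 bp therefore do not compare the widths of peaks. The strongest lay on chromosome 8 at 12523188 to 12523303, with summits of 45 and 37 reads in DMSO replicates 1 and 2 and a mean percentile rank of 97.4. The next was on chromosome 8 at 64023212 to 64023446, with peaks of 182 bp and 162 bp and summits of 22 and 31 reads. Another on chromosome 17 at 43971719 to 43971822 lay 188 bp from the centre of a common region. Others were on chromosome 19 at 70970 to 71071, chromosome 3 at 138640734 to 138640868, chromosome 14 at 106573096 to 106573213 and chromosome 7 at 123341713 to 123341814, with mean percentile ranks of 89.3, 89.0, 88.5 and 86.5. The remaining 5 had mean percentile ranks of 81.9 to 85.8. They lay on chromosome 16 at 28333148 to 28333259, chromosome 7 at 43818348 to 43818464, chromosome 20 at 23704415 to 23704572, chromosome 4 at 107819905 to 107820024 and chromosome 2 at 89459966 to 89460081. With peaks of at least 130 bp only, 2 of the 12 were still lost, with 150 bp 1 and with 200 bp 0. Here the widths of the regions' own DMSO peaks fixed the counts, which say nothing about signal in the tunicamycin libraries. With peaks up to 250 bp apart merged, 10 of the 12 were still lost.

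Within the 40447 common regions, a change of rank with tunicamycin was called at 21 sites. In a simulation the test recovered 86.5% of shifts of 2 normal-score units and 0% of shifts of 1 unit. The simulation gave every region the same spread, so these shares may not hold for the real lists. The rank comparison and its settings were chosen after the data had been examined. Each library's peaks were ranked by the caller's q-value over the same common regions, and the ranks were compared as normal scores with limma. After Benjamini-Hochberg adjustment 14 regions rose and 7 fell in rank in the tunicamycin libraries. This balance depended on single libraries: limma called 0 up and 4 down without tunicamycin replicate 1, so that none of the 14 was called, 1 up and 12 down without tunicamycin replicate 2, 18 up and 5 down without DMSO replicate 1, and 25 up and 2 down without DMSO replicate 2. Among regions with peaks of at least 130 bp in all 4 libraries it called 7 up and 9 down. For each of the 21, both tunicamycin ranks lay on the same side of both DMSO ranks. The 21 were called on these same ranks, so this separation is no further evidence. The same test on the other 2 splits of the libraries called 0 regions each with limma, with 1703 and 1533 regions at an unadjusted p under 0.05, against 2965 for the treatment split. With no change and a well-calibrated test, a share of 0.05 of the 40447 regions would lie under that level. The fits of the other 2 splits held no treatment term, so any difference between the groups widened their residual spread and lowered their calls. Their 0 calls are therefore no separate background. Across all common regions, both tunicamycin ranks lay above both DMSO ranks in 7265 regions (18%) and below in 7413 (18.3%), where chance gives 16.7% each way. The other splits gave 15.7% to 16.2% each way. Bar ties, each region separates the libraries along exactly 1 of the 3 splits. The shares of the other splits therefore fall as that of the treatment split rises, and are no separate background. Spearman's rho across these regions, which are not independent replicates, was 0.830 between the DMSO libraries, 0.842 between the tunicamycin libraries and 0.813 to 0.825 between groups.

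The risers included regions that were near the bottom of the common set in control cells. A region on chromosome 21 at 45277515 to 45277845 moved from a mean percentile rank of 1.19 to 59.1, a score change of 2.56 ± 0.495 (SE, limma adjusted p = 0.0110). Another on chromosome 11 at 15074711 to 15075289 moved from 4.67 to 64.6 (2.33 ± 0.473, SE, limma adjusted p = 0.0179). The smallest adjusted p-value belonged to a region on chromosome 2 at 100630398 to 100630610, which moved from 35.3 to 94.4 (2.10 ± 0.344, SE, limma adjusted p = 0.00186), although its DMSO ranks were 10.5 and 60.1. The largest gain in percentile points, from 11.4 to 78.2, was on chromosome 13 at 22010025 to 22010239. On chromosome 16, the region at 86421140 to 86421348 reached rank 92.6 from 34.2. The other 9 risers lay on chromosomes 1, 2, 3, 8, 11 and 12 and gained 40.4 to 64.1 percentile points.

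The 7 regions that fell were mostly among the strong common regions in control cells. On chromosome 1, the region at 52623798 to 52624247 dropped from a mean percentile rank of 88.4 to 19.7 (score change -2.24 ± 0.379, SE, limma adjusted p = 0.00198). A region on chromosome 5 at 153749794 to 153750003 dropped from 67.8 to 4.55 (-2.18 ± 0.443, SE, limma adjusted p = 0.0179), and one on chromosome 16 at 16143096 to 16143258 from 87.9 to 23.1 (-1.95 ± 0.354, SE, limma adjusted p = 0.00446). On chromosome 19, the region at 18499339 to 18499531 moved from 87.2 to 27.4 (-1.77 ± 0.344, SE, limma adjusted p = 0.0110). The remaining 3 kept ranks near or above the middle of the set after tunicamycin. They lay on chromosome 5 at 148442595 to 148442937 (95.7 to 54.6), on chromosome 16 at 56965778 to 56966234 (93.1 to 49.7) and on chromosome 4 at 775543 to 776277 (99.5 to 87.1). The 21 calls rested on a prior spread that follows the mean score, and 20 of them were also called among 25 when peaks were ranked by summit pileup. By contrast, limma with a constant prior spread called 0 regions, with 2821 at an unadjusted p under 0.05, and ranking by fold also called 0, with 2829 at that level. The lowest adjusted p-values were then 0.406 and 0.0630. The counts of 2821 and 2829 are to be read beside the share of 0.05 of the 40447 regions that chance gives. Single libraries also decided calls: of the 21, limma called 3 without tunicamycin replicate 1, 6 without tunicamycin replicate 2, 10 without DMSO replicate 1 and 11 without DMSO replicate 2.

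**Figure D3:**
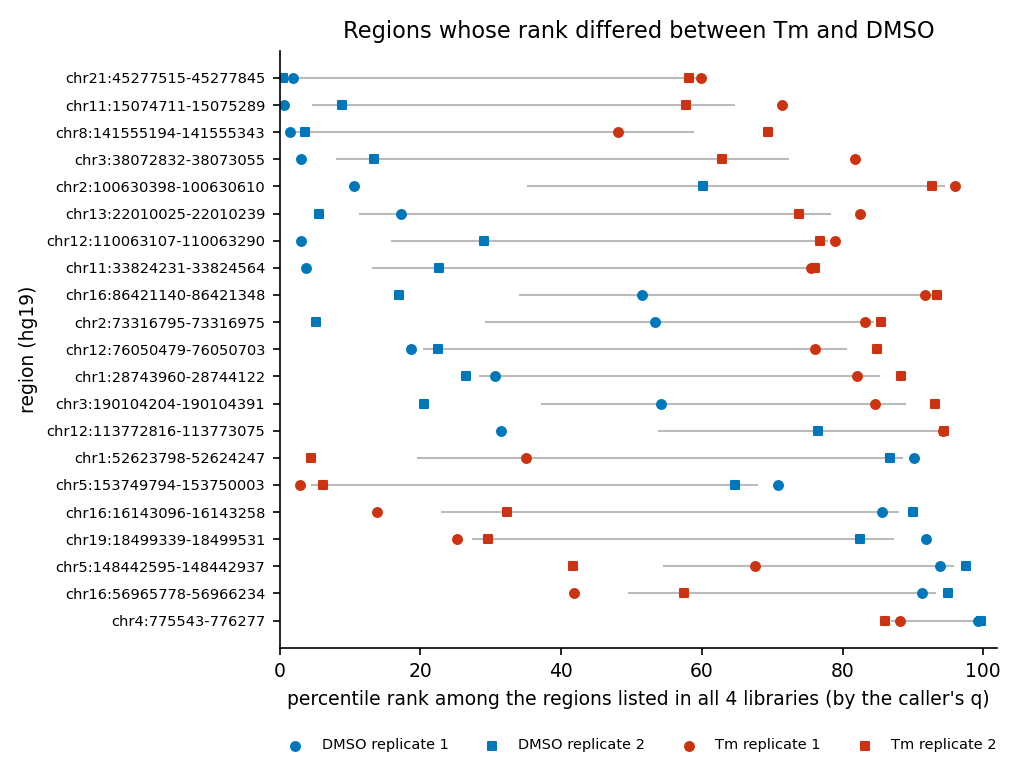
Percentile rank (horizontal axis) of the 21 regions called by limma, in each library, among the 40447 regions listed in all 4 libraries; each row is a region with its hg19 position, circles are replicate 1, squares replicate 2, and grey lines join the group means. The 14 risers are above and the 7 that fell below. In each row both tunicamycin points lie to one side of both DMSO points, which calling on these ranks favours.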

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

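The alternatives at a −log10 q of at least 20, in the top 40000, 20000 and 10000 peaks, at every fold and width limit, above the 25th, the 40th, the 60th and the 70th percentile, and for every setting of the rank comparison were chosen after seeing the data. The ratio of the treatment split to the higher other split, 1.36, ranged from 1.22 to 1.47 over 16 alternatives, and the mean number of peaks was higher after tunicamycin in 15, by 1.03-fold to 1.22-fold. The ratio of gained to lost regions, 1.97, was 2.27, 3.01 and 4.23 at a −log10 q of at least 5, 10 and 20, and 2.39, 2.80, 3.48 and 4.36 at folds of at least 6, 8, 10 and 15. It was 1.74 and 1.51 at widths of at least 150 and 200 bp, 1.79 with reciprocal overlap, and 2.68, 2.67, 3.27, 2.45 and 1.81 above the 25th, the 40th, the 50th, the 60th and the 70th percentile of both lists. With lists of equal length it was 1.09, and 1.047, 1.00 and 1.01 in the top 40000, 20000 and 10000, where equal totals push the ratio toward 1 by construction. Stricter limits leave fewer regions. Limits on q, fold, width and list length were applied to every list before merging. A region gained or lost under them could therefore hold a peak outside the limit in the other group. The percentile limits kept the definition of the full lists. Lost regions, 1462, numbered 779 and 390 at a −log10 q of at least 10 and 20, 784, 577 and 281 at folds of at least 8, 10 and 15, and 636 at 200 bp. Gained regions, 2878, numbered 1650 at a −log10 q of at least 20, 1225 at a fold of at least 15, and 1814 and 958 at 150 and 200 bp. The top 40000 gave 1395 gained regions, the top 20000 803 gained and 803 lost, and the top 10000 506 and 501. Above the 25th, the 40th, the 50th, the 60th and the 70th percentile 789, 312, 170, 81 and 29 were gained and 294, 117, 52, 33 and 16 lost. Leaving out a library loosens the definition, since 1 library then stands for its group, and does so unequally for gained and lost regions. The ratios that follow are therefore not comparable with 1.97. Without DMSO replicate 1 5967 were gained and 5191 lost (ratio 1.15), and without DMSO replicate 2 5937 and 5130 (1.16). Without tunicamycin replicate 1 the numbers were 8972 and 2931 (3.06), and without tunicamycin replicate 2 7134 and 4036 (1.77). The gap in Jaccard index, 1.34 points, was 1.63 and 1.78 at a −log10 q of at least 10 and 20, 1.59, 1.63, 1.73 and 1.70 at folds of at least 6, 8, 10 and 15, 1.08 and 1.502 in the top 20000 and 10000, and 1.59 points as a share of peaks with reciprocal overlap (the cause was not tested). Using all sequences moved nothing, because the lists hold no others. The replicate numbers were not treated as pairs, since the difference between replicates 1 and 2 in one group correlated with that in the other at 0.0132 across regions. With the replicate block, 2905 regions were gained and 1483 lost, and the rank comparison called 35 regions, including the 21. Ranking by fold gave 0 calls and a constant prior spread 0 (the cause was not tested), ranking by summit pileup 25, a robust prior 26, and peaks of at least 130 bp 16. Leaving out a library, with the lone one assumed to vary like the other group, gave 4 to 27 calls: 23 without DMSO replicate 1, 27 without DMSO replicate 2, 4 without tunicamycin replicate 1 and 13 without tunicamycin replicate 2. At 130 bp 12 of the 21 could be tested. The planned promoter, gene list and motif results and their alternatives were not run, for want of an hg19 annotation and genome in use. The low summit pileup limits the absences, since the median gained region carried 9 reads, and so does the smallest width of 100 bp.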

Other observations

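The tests in this part were chosen after the results they bear on had been seen, except those of the rank shift of neighbours and of the distance to common regions, whose predictions were written first. Gained regions were spread over the genome much like mixed regions. A common region lay within 5 kb of 34.8% of gained regions, 36.9% of lost regions and 35.2% of mixed regions, and gained regions lay a median of 9968 bp from the nearest one. For the hypothesis that gained regions lie closer to common regions than mixed regions do, no difference passed two-sided Fisher's exact test (adjusted p = 0.707 over 3 comparisons). Of 46 chromosome comparisons, 2 had an unadjusted p under 0.05 and 0 an adjusted one. Chromosome 12 held 97 lost regions, 6.63% of them against 4.85% of mixed regions (Fisher's exact p = 0.00717, adjusted p = 0.262), and chromosome 6 held 189 gained regions, 6.57% against 5.24% (Fisher's exact p = 0.0114, adjusted p = 0.262).

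Neighbourhoods of gained regions were tested in 2 ways, in view of the interest of the series in enhancer networks. If gained regions lay in clusters, more of them would have another gained region within 50 kb than random regions missing from at least 1 list. The count was 555 of 2878, against a mean of 529 and a 95% range of 477 to 584 over 2000 draws (permutation p = 0.342, adjusted over 6 patterns p = 0.737). If whole neighbourhoods opened together, common regions within 50 kb of gained regions may have risen in rank with tunicamycin. Their mean shift was -0.151 percentile points over 2429 gained regions, against -0.402 to 0.255 for random regions (10000 draws, permutation p = 0.658, adjusted p = 0.789). For lost regions the corresponding values were 166 of 1462 clustered regions (adjusted p = 0.737) and a shift of 0.331 points toward DMSO (adjusted p = 0.442). A p-value that misses the threshold does not exclude a smaller effect, and the ranges give the sizes that these lists could not have told from chance.

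More regions were gained than lost, 2878 against 1462. Longer lists after tunicamycin are left open as an explanation: the ratio of gained to lost regions was 1.09 with lists of equal length, but equal totals bring it toward 1 whatever made the lists longer. Deeper sequencing after tunicamycin is left open too. The mean genome-wide background of the tunicamycin libraries was 0.986 times that of the DMSO libraries (exact permutation p = 0.667), a gap smaller than that between the 2 DMSO libraries, 0.140 and 0.147, and a measure of depth only if reads were extended alike. A general rise in accessibility was not tested.

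Gained and lost regions together outnumbered the regions of the other 2 splits. Random differences of calls near the threshold would give all 3 splits alike, and they are argued against as the whole cause by the ratio of 1.37 to the higher other split with lists of equal length, where the other splits differed by 2968 against 2957. Treatment and handling shared by the 2 libraries of a group cannot be told apart, because the labels give no preparation batches and only 3 splits exist. If the mean mixed pattern is what chance gives, 1481 of the 2122 gained regions at equal list length could have arisen without treatment, so a single gained region is weak evidence of a change.

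The strongest gained regions were narrow, with 62.9% under 130 bp. A property of regions gained with tunicamycin is argued against, since 74.7% of mixed regions of the same ranks were as narrow, against 4.0% of common regions. A candidate explanation is the smallest width in the lists, 100 bp: a sharp summit whose peak is a few bases too narrow in a library drops out of that list whatever its height. On this reading, regions with peaks of at least 150 bp in both lists (251 gained, 153 lost) are less exposed to the limit. Only 9 and 6 of these rank above the 50th percentile of both lists, beside 8, 3, 1 and 3 in the mixed patterns. Nearly all are therefore weak calls, and the strong ones are few in every pattern. The narrow regions need the read coverage in the other group before they are called gained or lost.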
